A study of Capra hircus with 24 samples.

How the data were processed

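Goat skin was profiled in 24 samples. Per the labels, DNA was extracted with a DNeasy spin column kit, converted with Lightning bisulfite reagent and made into libraries with the Pico Methyl-Seq kit. Per the submitters' processing notes, fastp, Bismark and HOMER were used, without versions. Their roles here, order and settings, the genome build and whether copies of a fragment were removed were not given in the sources used here. The labels do not say whether each sample is a separate animal.

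Each sample had 3 deposited tables, for cytosines followed by G (CpG), by HG (CHG) and by HH (CHH). Per the file headers, each line gave a sequence, a position, a strand, the coverage, and the shares of C and of T. The deposited coverage was a count of calls per cytosine, and the deposited shares were percent of that count. Coverage times the share of C was a whole number to within 0.0306 calls, so methylated calls were recovered by rounding that product. The tables listed CpG cytosines with at least 4 calls and CHG and CHH cytosines with at least 10, as tested on the values, so a lightly covered cytosine is missing from them. Because copied fragments also reach the minimum, intervals here cover counting error only.

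The sequences carried RefSeq names. A table of goat genes from the assembly ARS1.2 gave gene names, chromosomes and positions without strand, and no genome sequence was used. Whether its positions suit the files was tested from the data: each of the 29 autosomal sequences was scored against the genes of each chromosome, by the share of its protein-coding genes whose CpG-richer end there held at least 20 listed CpGs and lay below 20% methylation. This step alone used methylation to place genes, so low gene ends helped decide the assignment. For each chromosome, 1 sequence scored 34.8% to 65.0% and every other at most 8%, and no sequence was chosen for more than one chromosome. The X genes were split between a pair of scaffolds by CpG counts alone, which placed 287 gene ends with at least 20 CpGs, against 15 with the scaffolds swapped. Positions printed here are those of the first and last listed CpG of a window, in the coordinates of the files. Exons, introns and CpG islands were not used here.

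The plan made before the data were examined called for promoters. Without strand, the end of each protein-coding gene with more listed CpGs, counted over all libraries and without looking at methylation, took the promoter's place, with a window from 1000 bp outside to 500 bp inside. This end need not hold the transcription start, so genes whose richer end had at least 2 times the CpGs of the other were also taken alone. CpGs on both strands were joined. In all, 12515876 CpGs were listed in any library, and 5511032 of the 11052250 autosomal ones were listed in 1 library only and 55157 in at least 12.

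A level is methylated calls over all calls, with a 95% Wilson interval. Region classes were formed in the order CpG-richer ends, CpG-poorer ends, bodies of genes of any kind, and the space between genes. The plan asked for gene ends with at least 5 CpGs and 30 calls in at least 12 libraries. This held for 916 of 19063 autosomal genes, with 3 or more members in 3 of the 16 lists, so list values use calls summed over the libraries, with at least 5 CpGs, 30 summed calls and 3 libraries. That choice was made after the depth had been seen, and the number of calls in the alternative of at least 100 calls was likewise taken over the sum. Summed levels weigh deeper libraries more. Each list median was set against 10000 random lists of the same size matched on the number of listed CpGs, and the summed calls of a list against 1000 of them in each library where the list had at least 100 calls. The result describes these libraries and is not a test over animals. All 16 lists, with 393 genes and no gene in more than one list, were written before the data were examined. The rule for named genes, written for the 12-library minimum and applied to the summed levels after the depth was seen, gives the 2 highest and 2 lowest measured members of each list, any member of the heat shock and imprinted lists, and, of the genes measured in at least 20 libraries, the 10 with the widest interquartile range; genes known by a number only are not named, and some genes that the rule gives are not reported here. HSPA1A and other list genes without a match in the gene table were not analysed here.

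Differences between libraries were tested with a chi-square test of methylated and unmethylated calls, with Benjamini-Hochberg adjustment, and relations over libraries with permutation tests of 100000 resamples. The steps were tested on simulated data. For the chi-square test over 931 gene ends, 19% of ends with a shift of 10 points in some libraries and 100% with a shift of 30 points were found, and 0.821% of unchanged ends were called. Those calls were drawn independently, with 1 level for all CpGs of an end in a library. They lacked the excess spread of the real calls, so these shares do not carry over to the real data. For random lists of 20 of 17804 gene ends, 7% of unshifted lists fell outside the central 95%, and 88% of lists raised by 40 points were found above it. The simulated levels did not depend on the number of listed CpGs, as real levels do, so these shares do not carry over either. Of 40 unrelated pairs of simulated measures, 2.5% had a permutation p under 0.05. No library was a copy of another: over 276 pairs, at most 18.7% of shared cytosines had the same calls, with a median of 16.3%. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9 were used. Alternatives varied the coverage minimum, the gene-end window, the weighting of sites, the matching of random lists, the dispersion and the libraries used.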

Results

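The series profiled DNA methylation in goat skin (Capra hircus) by bisulfite sequencing, which reads an unmethylated cytosine as thymine and leaves a methylated one as cytosine. Its title, in other words, concerns how well indigenous goat breeds withstand summer heat. The labels named 24 samples by a number and a letter, such as 1D and 2C, and gave the breed of each as NA, so no sample could be placed in a breed, season or treatment group. Each of the 24 libraries was therefore described by itself, with the median and range over libraries, and no group of animals was compared with another. A library listed a median of 1085358 nuclear CpG cytosines, from 230340 in 4C to 2110187 in 5C, and the median cytosine carried 4 calls in every library. Total nuclear CpG calls ran from 1031807 in 4C to 10639415 in 5C.

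Goat skin DNA was methylated at most CpG calls and at few others. The CpG methylation level was 69.6% at the median library, with the lowest value in 14C (66.4%, 95% Wilson interval 66.4% to 66.4%) and the highest in 8C (71.1%, interval 71.0% to 71.1%). Single sites mostly read near one extreme, since 51.8% of cytosines at the median library lay above 80% and 14.4% below 20%. The median cytosine had 4 calls. At 4 calls, a reading above 80% needs every call methylated and one below 20% needs none. Counting error thus adds to both extremes, and its part was not separated. Outside CpG, the level was 0.642% at CHG (range 0.554% to 0.817%) and 0.991% at CHH (range 0.701% to 1.69%), where H stands for A, C or T. These levels rest on cytosines with at least 10 calls, against at least 4 at CpG. At the median library these were 89647.5 CHG and 214595 CHH cytosines. The highest CHH level, in 4C, rested on 20693 cytosines, and 202 of them at or above 50% carried 58.0% of its methylated CHH calls. An unconverted cytosine is also read as methylated, and such calls were not separated from methylation here. CHH exceeded CHG in 24 of 24 libraries, by 0.376 percentage points at the median. A few cytosines at or above 50% carried much of this signal, namely 38.8% of the methylated CHH calls and 13.9% of the methylated CHG calls at the median library. With those cytosines left out, CHH still exceeded CHG in 24 of 24 libraries, by 0.0678 points at the median. Mitochondrial CpG cytosines had a level of 1.95% at the median library, from 0.742% in 11C to 4.72% in 4C, on 381 to 1787 calls, and lay below the nuclear level in 24 of 24 libraries. Mitochondrial CHG and CHH cytosines had nearly the same median level, 1.91% and 1.95%.

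Methylation fell to its lowest values at gene ends rich in CpG. The gene table used here gave no strand, so the end of each protein-coding gene with more listed CpGs stood in for the promoter. It need not hold the transcription start, so a high level at a single gene need not be that of its promoter. Over the window from 1000 bp outside to 500 bp inside that end, the level was 21.2% at the median library, from 14.1% in 14C to 24.6% in 16C. Gene bodies stood at 74.1% and the space between genes at 71.4%. The gene bodies exceeded the CpG-richer ends by 53.3 points at the median library and in 24 of 24 libraries, with a smallest difference of 49.4 points in 18C and intervals that did not overlap in any library. The CpG-poorer ends of the same genes lay at 67.0%, 46.3 points above the CpG-richer ends at the median and above them in 24 of 24 libraries. Gene bodies exceeded the space between genes by 2.5 points, again in 24 of 24 libraries, and this small difference was 0.142 points when the gene end was taken as the 2000 bp outside the gene and 6.66 points with sites of at least 10 calls. The intervals covered counting error only, and the widest half-interval of any such autosomal difference was 0.909 points.

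**Figure D1:**
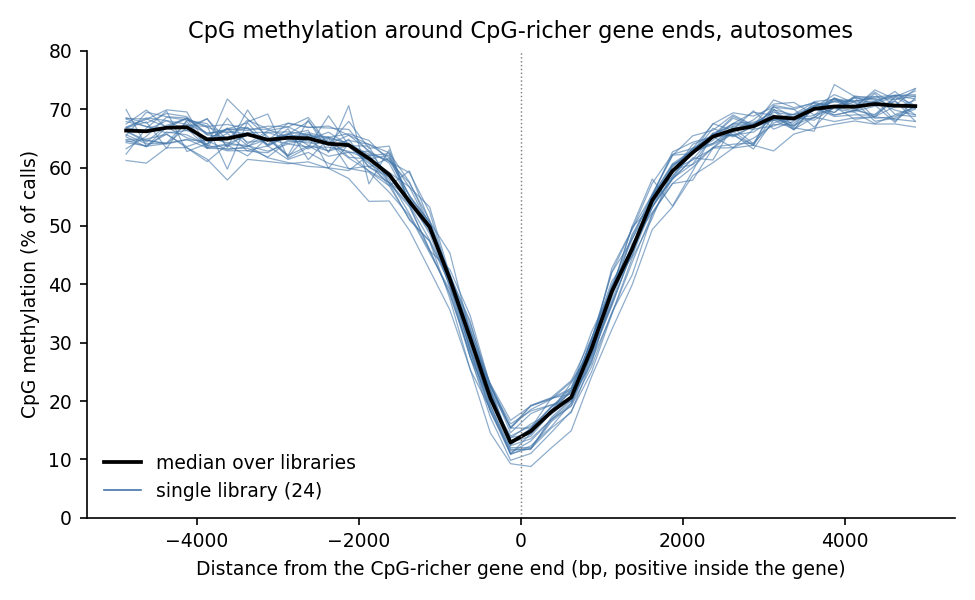
CpG methylation (percent of calls) in 250 bp steps from -5000 to 4999 bp around the CpG-richer end of autosomal protein-coding genes, negative outside the gene, with a thin line for each of the 24 libraries and a thick line for their median. The median is 12.9% in the step just outside the end, 66.3% in the outermost step and 70.5% in the innermost step.

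**Figure D2:**
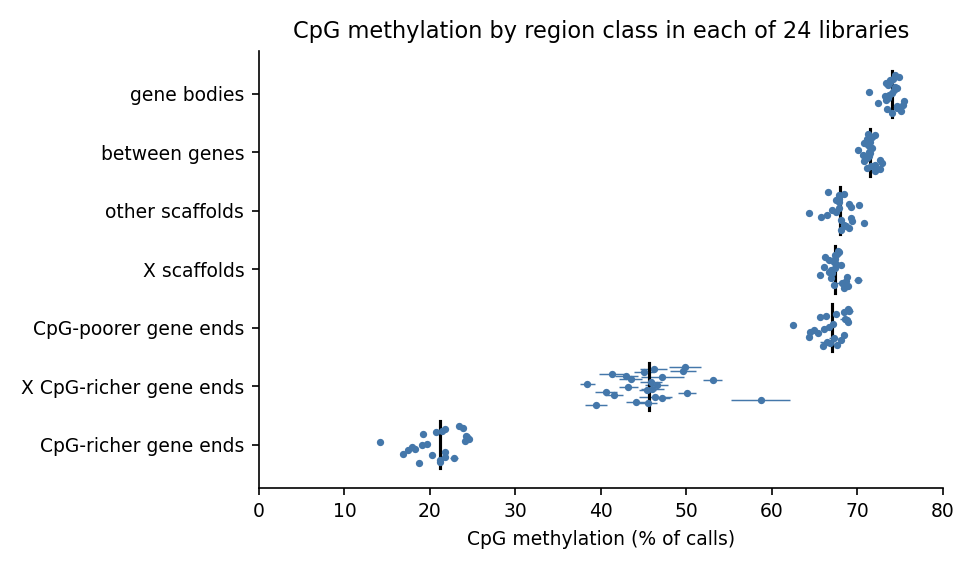
CpG methylation (percent of calls) by region class, with a point for each of the 24 libraries, bars for 95% Wilson intervals and a vertical line for the median. CpG-richer autosomal gene ends lie between 14.1% and 24.6%, X gene ends between 38.4% and 58.8%, and gene bodies between 71.4% and 75.4%.

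The level was lowest where listed CpGs were densest. Autosomal bins of 500 bp with 1 to 4 listed CpGs had a level of 73.9% at the median library, bins with 5 to 9 had 74.4%, bins with 10 to 19 had 70.7%, bins with 20 to 29 had 60.3%, and bins with 30 or more had 33.4% (range 22.2% to 38.7%). With calls summed over the libraries, 17308 autosomal gene ends could be measured, on a median of 331 calls from 14 libraries. Of these, 10875 lay below 20%, 4464 between 20% and 80%, and 1969 above 80%. Among the 13555 ends with at least 20 listed CpGs, 75.8% lay below 20%, against 15.9% of the 3753 ends with fewer.

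Genes of the heat shock response, which refold or hold proteins that unfold in heat, were unmethylated at most of their CpG-richer ends. Of the 34 measured members of the list of heat shock factors and chaperones, 28 lay below 20%, 5 between 20% and 80% and 1 above 80%, with a median of 2.22%. HSF1 and HSF2, transcription factors of the heat shock response, had 0 methylated calls of 468 and of 768, with upper 95% Wilson bounds of 0.81% and 0.5%. HSP90AB1, a cytosolic HSP90, lay at 0.340% and HSPD1, the mitochondrial chaperonin, at 0.290%. HSPA5, the chaperone of the endoplasmic reticulum, lay at 2.17%. Of the 6 members at or above 20%, 5 were small heat shock proteins, namely HSPB3 at 86.1% (95% Wilson interval 82.1% to 89.4%, chromosome 20, 24699587 to 24700008), HSPB7 at 56.9%, HSPB8 at 31.6%, and CRYAB and HSPB2, which share a CpG-rich stretch, at 30.2% and 22.1%, and the other was a gene without a symbol at 75.2%. No list of small heat shock proteins was set beforehand, those below 20% were not counted here, and the grouping was not tested. HSP90AA1, the inducible HSP90, had 15.5% over 562 calls, but its 7 libraries with at least 30 calls ranged from 0% to 77.8%. The list median lay at percentile 9.33 of 10000 random lists matched on CpG count, inside the central 95%, and the list's summed calls were above the random lists in 2 of 24 libraries. No heat shock gene end reached 30 calls in 12 libraries, so variation between libraries was not tested for these genes.

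The list of further candidates for heat tolerance, drawn from hormone, antioxidant and immune genes, was mixed. Of 35 measured members, 21 lay below 20%, 12 between 20% and 80% and 2 above 80%, with a median of 13.8% at percentile 61.1. SOD1, a superoxide dismutase, and NFE2L2, a regulator of antioxidant genes, had 0 methylated calls of 369 and of 433. The highest members were NOS2, the inducible nitric oxide synthase, at 80.2% (interval 73.8% to 85.4%) and IL1B, a cytokine of inflammation, at 80.2% (interval 72.2% to 86.3%).

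Genes of cell types of the skin had both low and high gene ends, and of the 5 such lists the keratinocyte list alone lay outside the central 95% of its random lists. Of 21 keratinocyte genes, 8 lay below 20%, 11 between 20% and 80% and 2 above 80%, and the list median of 39.6% was at percentile 98.3. That median was 17.4% in genes whose ends differed at least 2-fold in CpGs and 58.9% over the 2000 bp outside the gene. ITGA6, an integrin of basal keratinocytes, lay at 2.04% and KLK7, a protease of the cornified layer, at 2.00%, while ITGB4 and LAMB3, both parts of the attachment to the basement membrane, lay at 84.2% and 81.0%. Of 17 hair follicle genes, 9 lay below 20%, including FGF5, a regulator of hair length, with 0 methylated calls of 625, and SOX9 at 2.21%. The keratin genes KRT74 and KRT27 of this list lay at 87.9% and 82.4%. The list median was 14.9% at percentile 45.4. Of 12 melanocyte genes, 6 lay below 20%, among them MITF at 0.540% and PMEL at 0.780%, and the pigment genes SLC45A2 and DCT lay at 90.9% and 82.3%, with a list median of 38.1% at percentile 70.2, which was 14.1% with at least 100 calls per gene end and 15.4% with the window of 500 bp on each side. Of 17 dermal fibroblast genes, 10 lay below 20%, with COL5A2 at 0% on 42 calls and VIM at 0.350%, against COL5A1 at 85.9% and LUM at 93.2% on 44 calls, and the median was 14.4% at percentile 57.7. Of 11 endothelial genes, 4 lay below 20%, with FLT1 at 1.29% and KDR at 1.52%, against TIE1 at 93.0% and PECAM1 at 85.7% on 42 calls, and the median was 60.7% at percentile 91.1. This median was 31.6% with at least 100 calls per gene end and 32.4% in genes whose ends differed at least 2-fold in CpGs. The other alternatives with a median gave 54.6% to 65.3%.

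Immune cell genes were methylated at most ends. Of 19 members, 1 lay below 20%, 9 between 20% and 80% and 9 above 80%, with a median of 76.3% at percentile 98.9. CD8A and CD3E were lowest at 19.2% and 32.7%, and LCK lay at 89.2%. Germline genes, which most body tissues keep silent, had the highest list median of the 16 lists, 83.3% at percentile 100, and were above the random lists in 20 of 20 libraries. PIWIL2 at 95.9% and DMRTB1 at 94.5% were highest and TDRKH at 5.75% and TDRD1 at 39.3% lowest. Of 11 hepatocyte genes, 0 lay below 20%, with a median of 78.3% at percentile 97.6, from APOA1 at 32.3% and AHSG at 45.3% to TTR at 95%. Of 14 skeletal muscle genes, 9 lay between 20% and 80%, with a median of 46.6% at percentile 99.5, from ACTA1 at 2.53% and MYOD1 at 5.39% to MYOG at 80.1% and CKM at 80.9%. Neuron genes had a median of 5.09% at percentile 12.9, with 8 of 11 below 20%, NEFL and NEFM at 0% and RBFOX3 and ELAVL4 at 84.1% and 64.4%.

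Imprinted genes, which are expressed mainly from one parental copy, had 13 of 23 measured ends between 20% and 80%, with 7 below and 3 above. The list median was 34.6%, against 4.34% for the random lists, at percentile 100, and the list was above the random lists in 24 of 24 libraries. PEG3 lay at 44.6% (95% Wilson interval 41.25% to 48.0%, chromosome 18, 65583955 to 65585385), MEST at 42.2% (interval 38.1% to 46.4%) and IGF2 at 39.6%. PEG10 and SGCE, whose windows overlap on chromosome 4, lay at 36.1% and 34.6%. IGF2R had 0 methylated calls of 540 and IMPACT lay at 2.55%, while NNAT lay at 90.9% and RTL1 at 84.6%.

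Most measured gene ends of housekeeping genes and of regulators of development lay below 20%, as did 75.8% of all autosomal ends with at least 20 CpGs. Of 24 housekeeping genes, 19 lay below 20%, with a median of 1.71% at percentile 1.70, from PPIA with 0 methylated calls of 372 to GPI at 85.7% and VCP at 87.7%. Genes that write, erase or read DNA methylation had 13 of 15 ends below 20%, with a median of 4.48% at percentile 23.5, from DNMT3B at 0.2% and HELLS at 0.660% to MBD2 at 23.1% and ZBTB38 at 82.6%. Developmental transcription factors had 46 of 58 ends below 20%, 12 between 20% and 80% and 0 above 80%, with a median of 6.21% at percentile 81.5. HOXB9 had 0 methylated calls of 410, and HOXB5 and HOXC4 were highest at 69.8% and 68.5%.

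In all, 7 of the 16 lists lay outside the central 95% of matched random lists, 6 above and 1 below. The germline list stayed outside in each of 7 alternatives of window, coverage, matching, libraries and gene choice. The housekeeping list moved inside in 5 of them, at percentiles 2.69 without library 4C, the shallowest, 3.8 with at least 100 calls, 8.81 with sites of at least 5 calls, 13.1 with the window of 500 bp on each side and 23.1 with the 2000 bp outside the gene. The hepatocyte list also moved inside in 5, at 97.4 without 4C, 97.3 with 500 bp on each side, 96.9 with at least 100 calls, 91.5 with the 2000 bp outside and 93.5 with genes whose richer end had at least 2 times the CpGs of the other. Leaving out 4C thus left 5 lists outside. Among those genes of unequal ends, the immune list moved inside at 92.2 and the skeletal muscle list at 90.03. With unmatched random lists, the keratinocyte, skeletal muscle and imprinted lists moved inside at 97.3, 96.8 and 97.0. With the gene end taken as the 2000 bp outside the gene, the germline and immune lists stayed above the random lists and the neuron list fell below them at percentile 0.71. The keratinocyte, skeletal muscle and imprinted lists moved inside at 96.3, 92.8 and 93.1.

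**Figure D3:**
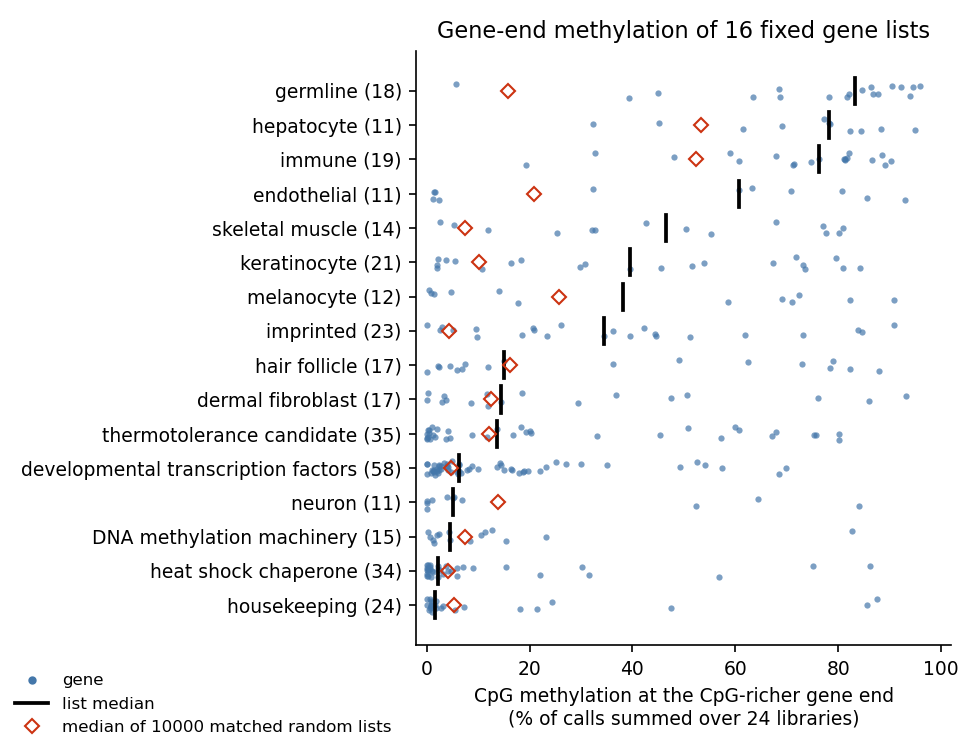
CpG methylation at the CpG-richer gene end (percent of calls summed over 24 libraries) for the measured genes of 16 gene lists, with the number of genes in brackets, a bar for the list median and a diamond for the median of 10000 random lists matched on CpG count. List medians run from 1.71% for housekeeping genes to 83.3% for germline genes.

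X gene ends were more methylated than autosomal ones. The CpG-richer ends on the X scaffolds had a level of 45.7% at the median library, against 21.2% on the autosomes, and exceeded the autosomal ends in 24 of 24 libraries, by 19.1 points in 17C to 35.9 points in 4C. The value of 4C rested on 771 calls, fewer than in any other library. Of the 287 X gene ends with at least 20 listed CpGs, 234 lay between 20% and 80%, 31 below and 22 above, with a median of 36.3% and quartiles of 28.6% and 45.6%. Of the autosomal ends with as many CpGs, 17.6% lay between 20% and 80% and the median was 4.58%. Across the whole X scaffolds the level was 67.4%, against 70.1% over all autosomal sites. In this comparison, added after the data were seen, the autosomes lay above by 2.48 points at the median library, from 0.000777 points in 14C to 3.70 points in 16C, with intervals apart in 23 of 24 libraries. The median difference turned to -0.544 points with sites of at least 10 calls, so its direction depended on the coverage minimum. The size of the X gene-end difference changed with the coverage minimum and the window, from 24.3 points with all listed sites to 48.7 points with sites of at least 10 calls, and was 14.0 points with the gene end taken as the 2000 bp outside the gene.

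**Figure D4:**
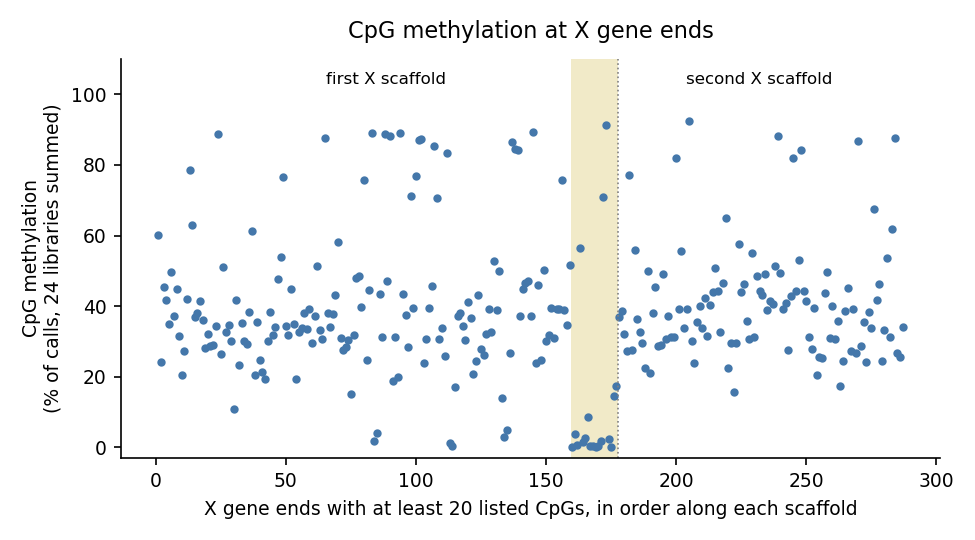
CpG methylation (percent of calls summed over 24 libraries) at 287 X gene ends with at least 20 listed CpGs, in order along both X scaffolds, which a dotted line separates. Most points lie between 20% and 80%, and 15 of the 18 ends in the shaded stretch, from TBL1X to the end of the first scaffold, lie below 20%.

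Some gene ends differed between libraries by more than the counting error of their calls. Only 21 autosomal gene ends had at least 30 calls in at least 20 libraries, and 18 of them passed a chi-square test of methylated and unmethylated calls over libraries at an adjusted p below 0.05 (Benjamini-Hochberg over 21 genes). The widest spread was at LNP1 (chromosome 1, 44486173 to 44487517), with an interquartile range of 23.9 points, a median of 22.6% and a range of 0% in 2C to 52.4% in 5C over 20 libraries (adjusted p = 3.41e-32). TNNI2, the inhibitory troponin of fast skeletal muscle (chromosome 29, 50654934 to 50656420), had an interquartile range of 19.5 points around 82.4%, from 44.9% in 17C to 95.3% in 15C (adjusted p = 8.19e-24). MIPEP, a peptidase of mitochondrial import (chromosome 12, 52456950 to 52458080), ranged from 0% in 21C to 43.2% in 1D (adjusted p = 4.57e-22). CXXC5 ranged from 0% in 4C to 22.1% in 8C around a median of 5.46%. ACTL8 at 79.1% and POU2AF1, a coactivator of B cells, at 84.0% had interquartile ranges of 8.11 and 7.56 points, and THOC1 at 0% had 1.82 points. The other 3 of the 10 widest ends belonged to genes without a symbol. Calls on one read or from copies of one fragment are not independent, and the chi-square was 3.00 times its degrees of freedom at the median gene. Divided by that factor, 6 of 21 gene ends passed. Real differences between libraries raise the factor too. So can the CpGs covered, since each library listed its own set of CpGs within a window. Over all autosomal ends, the median level ran from 12.9% just outside the end to 40.9% at 751 to 1000 bp outside it. These sources were not separated from dependent calls.

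No relation between the CpG level of a library and its depth was detected by a permutation test, which leaves a weak relation open. Over 24 libraries, Pearson's r between total CpG calls and the CpG level was -0.0363 (two-sided permutation p = 0.866, adjusted p = 0.866 over 3 relations) and Spearman's rho was 0.106 (p = 0.621). Without 5C and 16C, the libraries farthest from the median depth, r was -0.282 (p = 0.204). The labels gave no batch within which to repeat the test.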

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

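No paired analysis was possible because the labels give no groups. The alternatives were chosen before the data were examined, except the gene ends with at least 2 times the CpGs of the other end and the variation over gene ends in at least 12 libraries, which were added after. For the lists, the rule of at least 12 libraries was the plan, and the summed calls reported in its place were chosen after the depth was seen. Directions of the region differences held at the median library under each alternative, except that of autosomes and X scaffolds, a comparison added after the data were seen, whose 2.48 points became -0.544 points with sites of at least 10 calls. The cause of the shifts was not tested unless named. The median CpG level of 69.6% became 69.8% with sites of at least 5 calls, 64.0% with at least 10, 69.8% without the sites of highest coverage and 69.9% as a mean of site levels, where CHG and CHH became 0.628% and 0.888%. Minimums of 5 and 10 calls remove no CHG or CHH cytosine. The difference of gene bodies and CpG-richer ends, 53.3 points, became 51.4 and 44.8 points with at least 5 and 10 calls, 57.2 and 38.3 points with windows of -500 to +500 and -2000 to 0, and 53.6 points as a mean of site levels. The X gene-end difference became 26.6 and 48.7 points with at least 5 and 10 calls, and 27.7 and 14.0 points with those windows. The 7 lists outside the random lists became 3 with the window of -2000 to 0, 4 with genes of unequal ends, and 0 under the planned rule of at least 12 libraries, where only 3 lists kept 3 members. The 18 gene ends that varied became 9 of 12 tested with the window of -500 to +500, 3 of 3 with at least 5 calls, 6 of 21 with the dispersion, and 683 of 916 with ends in at least 12 libraries. Fewer ends were tested in the settings with counts of 9 and 3, and the window or the sites used changed too. The other 10 alternatives of these results stayed within their limits. Of the list medians and further region differences, 98 alternatives left the list's call or the difference in place, 18 ended a list's call, 4 added one, 16 moved a difference and 1, named above, turned its direction. The gene-end windows cannot change the X scaffold difference to all autosomes. Lists without a call crossed their random lists, with the window of -2000 to 0 from percentile 81.5 to 14.7 for developmental, 61.1 to 11.2 for heat tolerance and 70.2 to 23.7 for melanocyte genes. The added calls were the developmental list with the window of -500 to +500, the neuron list with that of -2000 to 0, and the heat shock and endothelial lists with unmatched random lists. A call in place does not mean a median in place. Leaving aside the rule of at least 12 libraries, the alternative medians ran from 14.1% to 38.1% for melanocyte genes, 31.6% to 65.3% for endothelial, 17.4% to 58.9% for keratinocyte, 9.30% to 25.6% for hair follicle and 9.57% to 40.3% for dermal fibroblast genes. They ran from 4.13% to 25.5% for the heat tolerance candidates, 0.738% to 15.6% for heat shock, 0.805% to 21.8% for housekeeping, 1.39% to 21.2% for the methylation machinery, 4.35% to 13.0% for developmental, 2.51% to 5.90% for neuron and 19.7% to 46.3% for imprinted genes. With genes of unequal ends, the keratinocyte, melanocyte, endothelial and heat tolerance medians fell to 17.4%, 17.7%, 32.4% and 4.13%. The imprinted median alone rose, to 35.3%. The germline, immune, hepatocyte and skeletal muscle medians moved least in proportion. Depth limits single genes, since 21 gene ends had 30 calls in 20 libraries.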

Other observations

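Of the tests below, those on the mix of covered sites, on DNA of one animal in 9C and 10C, and on developmental genes in low-methylated runs were set before their result was seen, as were earlier tests for mixed sexes and for mixed-in DNA, and the others after.

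Ends of developmental transcription factor genes lay in long stretches of low methylation more often than those of matched random lists. Over 683843 autosomal bins of 1000 bp, 4.45% were below 15% methylation, and 257 runs held at least 5 such bins in a row. The longest, 18 kb at LHX5 on chromosome 17 (10164000 to 10181999), had a level of 3.65% over 6077 calls. The next, 13 kb, lay at EN2, and runs of 10 to 12 kb lay at NEUROD2, BARHL1, PAX6, NKX2-2, LHX1, NKX2-1 and FOXD3, all transcription factors of development, named after their values were seen. A run of 12 kb on chromosome 18 at NLRP13, a gene of the NLRP family, was the longest at a gene of another kind, and runs of 11 kb on chromosome 11 and 10 kb on chromosome 25 held no CpG-richer gene end. Of the fixed developmental list, 22.4% of the measured genes, 13 of 58, had their CpG-richer end in a run, against 1.37% on average in random lists matched on CpG count (percentile 100). Of the neuron list, 2 of 11 did, 18.2% against 1.01% in its random lists (percentile 99.8). The hair follicle, dermal fibroblast and skeletal muscle lists each had 1 such gene, inside the central 95% of their random lists, and the other 11 lists had 0.

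Non-CpG cytosines at or above 50% recurred between libraries. A CHH cytosine at or above 50% in 1 library and listed in another was at or above 50% there in 91.4% of cases, against 0.331% of all listings, and a CHG cytosine in 77.4% of cases, against 0.109%. The cause of this recurrence was not tested. Mitochondrial CHG cytosines had 1.91% at the median library and lay above the nuclear CHG level in 21 of 24 libraries by intervals that did not overlap, and mitochondrial CHH cytosines had 1.95%, above the nuclear CHH level in 18 of 24 libraries and below it in 1. Among gene ends in at least 12 libraries, added after the data were seen, NAIF1 had the widest interquartile range, 66.8 points over 13 libraries, from 0% to 100%, and ANKRD31 the next, 62.2 points. Libraries can list different CpGs of such an end, which can widen these ranges.

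Low X gene ends lay next to one another along the scaffold. From TBL1X, a border chosen after the values were seen, to the end of the first X scaffold, 15 of 18 ends with at least 20 CpGs lay below 20%, with a median of 2.06%, while the other 269 X ends had a median of 37.2% and quartiles of 30% and 46.1%. The low ends there include GPR143, STS, PUDP, NLGN4X, PRKX, GYG2, XG and CD99, and the 3 others were ARSE at 91.4%, ANOS1 at 56.5% and a gene without a symbol at 70.9%. The stretch's listed CpGs numbered 8107 per Mb, against 2152 on the rest of the X scaffolds and 4482 on autosomes. Some ends share CpGs, and with those counted once, 13 of 16 ends in the stretch lay below 20%. The longest run of neighbouring ends below 20% was then 6, which 3 of 10000 shuffles of the order of 273 ends reached. Outside the stretch, 16 ends lay below 20%, among them the neighbours KDM6A at 1.70% and FUNDC1 at 4.15%, and EIF2S3 at 0.405%.

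The intermediate level of most other X gene ends was weighed against 3 explanations. A mixture of male and female animals would split the share of X calls, since a male carries a single X, but the lowest library had 0.832 of the highest share (2.15% of autosomal calls in 7C, 2.59% in 22C). An earlier test, written before its result was seen, used the X gene-end level instead; its lowest over highest library was 0.654, or 0.724 without 4C with its 771 calls, which left the question open, and the share of calls replaced it afterwards. Misplaced genes are argued against by 10 arbitrary placements, with all X genes moved by up to 1000 kb, which gave at most 40 CpG-rich ends in place of 287. An inactive X that spares a fixed list of 15 human escape genes would leave those genes low as a set. The median of the 10 measured was 32.9%, at percentile 26.0 of random X ends. Of them, 3 lay below 20%, PUDP at 0.336%, EIF2S3 at 0.405% and KDM6A at 1.70%, and the others lay at 27.5% to 39.3%. A median cannot show whether a part of the list was spared. Other low X ends, among them STS, NLGN4X, PRKX, XG and CD99, were not on that list. The result thus covers the listed genes as a set only and cannot decide for human escape genes as a whole. The limit to human escape genes was put into this explanation after its test had come out against the wider one. An inactive X in female animals that spares only a part of that list, or genes outside it, whether or not they escape in humans, stays open. It was not tested, as the labels name no sex.

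The CpG level ran from 66.4% in 14C to 71.1% in 8C. Incomplete conversion would raise CHG and CpG levels together, but their Pearson's r over 24 libraries was -0.654 (permutation p = 0.00056, adjusted p = 0.00084 over 3 relations, Spearman's rho -0.529, p = 0.00867, r = -0.583 without 14C and 4C). The CpG level in that test was not held to one mix of covered sites, so it cannot tell whether conversion added a part. The mix of covered sites stays open as a part. The level fell with the percent of autosomal calls in bins of 30 or more CpGs (r = -0.833, permutation p = 1.0e-05, the smallest these permutations can give, rho = -0.750, p = 6.0e-05, r = -0.733 without 14C and 7C). With the shares of calls in the bins of each CpG density held equal, the range of the autosomal level over libraries was 0.630 of its raw range. It was 3.38 against 5.36 points (66.1% in 14C to 71.5% in 23C), and the ratio lay between the bounds of 0.5 and 0.8 set for the test. Covered sites could still differ within bins of one density. The level in bins of 30 or more CpGs ran from 22.2% to 38.7%, so the mix was not held wholly equal. Sequencing depth stays open too, since r with total calls was -0.0363 and its spread over 24 libraries is wide. No biological explanation was tested, as no label gives a group.

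Pairs of libraries were compared at variable CpGs, which were at or below 10% in some of the other libraries and at or above 90% in others, with at least 75% of those libraries at one end or the other. Over 276 pairs the median r was 0.363, and 9C and 10C had the highest, 0.463 (chromosome-jackknife SE 0.0198, 2081 sites), followed by 17C and 18C at 0.462 (SE 0.0291) and 16C and 24C at 0.448 (SE 0.0179). Counting noise stays open, since the pair was picked as the highest of 276. With alternate chromosomes put into 2 sets, 9C and 10C ranked 5 in one set and 2 in the other, so neither set alone picked them. They lay 2.70 SE above the median pair in the set where they stood lower and 6.35 SE above it in the other. Mixed-in DNA of another animal also stays open. It would raise the share of intermediate levels, which also rose with depth, and against a fit on depth through the other 22 libraries 9C lay at 0.193 SD and 10C at -0.722 SD, which leaves room for a modest mixture. An earlier test, written before its result was seen, set the 41.6% of 9C and 41.8% of 10C against the 35.2% to 46.0% of the others, and was replaced because that range ran from the shallowest library, 4C, to one of the deepest, 16C. One animal's DNA in both stays open, since the r between the strands within 10C, at the variable sites of the pair, was 0.482 (SE 0.0416), within 2 SE of the pair. That test separates weakly, as the strand r at each library's own variable sites, 0.466 in 10C, was above the r of the pair in only 8 of 24 libraries. Related animals would also stay open and were not tested.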
